A study of Mus musculus with 4 samples.

How the data were processed

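The labels describe 4 libraries of bone marrow-derived macrophages from C57BL/6 mice aged 8 to 10 weeks, 1 each of wild-type unstimulated, wild-type LPS, miR-7 deficient unstimulated and miR-7 deficient LPS cells. How the deficiency was made, the sex of the mice and the origin of the deficient line are not given in the sources used here. Per the series design text, RNA was purified with TRIzol, enriched for poly(A) and sequenced on a HiSeq 2000. Base calls came from Casava v1.8.2, Cutadapt trimmed the reads, TopHat v2.0.13 with Bowtie2 aligned them, and exon annotation was retrieved with Partek. The submitters' processing notes name HTSeq as a tool and mm8 as the genome build. The authors deposited raw counts per gene, 1 file per library, with no normalization, and all values were whole numbers of at least 0. Strand setting, handling of reads with several positions and annotation release are not stated.

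Each file held the same 52550 versioned gene IDs. Without versions, 52403 IDs (99.7%) matched GENCODE M21 on GRCm38, and with versions 49035 (93.3%), so symbols, coordinates and gene types were taken from the M21 gene with the same ID, whatever build the reads were aligned to. Total counts were 40745230, 39178290, 33937823 and 42074624. The 37 mitochondrial IDs had 0 counts in every library. Of all IDs, 11430 share exonic bases with another gene. No 2 libraries were identical.

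The following choices were made before the data were examined: groups, comparisons, tests, gene lists, marker lists, the naming rule and the alternatives, apart from 5 kinds added later. Genes with a CPM of 1 or more in at least 2 libraries were tested, 12730 in all. TMM factors were 1.15, 0.846, 1.16 and 0.890. An additive model of genotype and LPS was fitted to the 4 libraries with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with p adjusted by Benjamini-Hochberg and called under 0.05. It leaves 1 residual degree of freedom, the genotype by LPS term, so an effect of genotype that depends on LPS counts as spread. The biological coefficient of variation was 0.247 and the prior degrees of freedom 5.18. Standard errors were derived from the test, as the size of the fitted log2 fold change divided by the square root of its F statistic. Beside that model, each pair of libraries was compared by the log2 ratio of TMM-scaled counts with an exact Clopper-Pearson 95% interval, and the difference between LPS effects by a ratio of ratios with a normal 95% interval after adding 0.5 counts. A gene counted as beyond 2-fold where its whole interval was. Intervals and floors cover counting error only, since reads of PCR copies are not independent molecules, and tests across genes compare libraries, not conditions. Folds against 0 counts were computed against a floor of 3 counts in that library, 0.0713 to 0.0884 CPM of its unscaled total.

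For each of 22 gene lists and 14 marker lists, members past the test were counted over all genes and again adjusted over the list alone, and medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins. The lists covered cytokines, chemokines, interferon-stimulated genes, NF-kB and feedback regulators, the TLR pathway, inflammatory effectors, inflammasome, antigen presentation, alternative activation, macrophage identity, replication, mitosis, cholesterol synthesis, LXR and lipid handling, glycolysis and hypoxia, TCA cycle and oxidative phosphorylation, lysosome, unfolded protein response, antioxidant genes, reported miR-7 targets, miR-7 loci and partners, and microRNA machinery. Seed sites of miR-7 were searched in the longest annotated 3′ UTR, and medians were placed among random lists matched on expression (10 bins) and UTR length (5 bins).

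Named genes followed a fixed rule. For LPS, they were the 10 highest and 10 lowest fitted changes among called genes with a log2 ratio of at least 1 in size and the same sign in both genotypes and a CPM of 10 or more in at least 1 library. For genotype, they were the 10 highest and 10 lowest by the interval bound nearest 0 of the smaller of the 2 ratios, with a CPM of 5 or more in at least 1 library. For each pair, and for the difference between LPS effects, the 5 highest and 5 lowest were taken, and from each list up to 4 members, 2 by mean CPM and 2 by change. Entries with provisional names were counted but not named, apart from Oip5os1, which is a list member. A set of macrophage and miR-7 genes was always given, apart from some results that are not reported here.

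Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a CPM of 10 or more, thinned counts, other fold limits, DESeq2's Wald test, models with 1 factor, leaving out each library from a model of LPS, Spearman correlation, a pseudocount of 5, unmatched random lists, and other UTR and matching choices. After the data were seen, 5 kinds were added: no genes that share exonic bases, no genes on X and Y or pseudogenes, list members that share no exonic bases, a model of genotype alone with each library left out, and wild-type unstimulated counts less 1.81% of the wild-type LPS counts, the share seen for 53 strongly induced genes.

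The model was tested on simulated data with 50 genes changed at each size. It recovered 32% of 2-fold changes for LPS and 26% for genotype, 92% and 94% of 4-fold changes, and 98% and 100% of 8-fold changes. It also called 26 and 22 unchanged genes, beside 16, 46, 49 and 50 changed genes for LPS and 13, 47, 50 and 50 for genotype. The changed genes are listed by fold, 2, 4, 8 and 16. The share of false calls in this simulation was thus above the limit set on the adjusted p. That share was not measured in the data themselves. Intervals covered the true value for 96.6% of 4000 simulated genes for pairs and 95.8% for the difference between LPS effects.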

Results

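Polyadenylated RNA was sequenced from bone marrow-derived macrophages, cells grown from marrow progenitors, of wild-type mice and of mice deficient in the microRNA miR-7. Cells of each genotype were left unstimulated or given LPS, the bacterial outer-membrane lipid that activates Toll-like receptor signalling, at 100 ng/mL for 12 hours. Each of the 4 groups held 1 library. Gene counts summed to 40745230 in the wild-type unstimulated library, 39178290 in the wild-type LPS library, 33937823 in the deficient unstimulated library and 42074624 in the deficient LPS library. Of 52550 gene entries, between 18156 and 18613 had at least 1 count in a library, and 12730 were tested. Values are CPM, counts scaled to library size after TMM normalization, and a series of 4 values follows the order of libraries just given. Fitted log2 values carry a standard error from a model of all 4 libraries. In it, the 2 LPS pairs, or the 2 genotype pairs, stood in for replicates. A difference between the mice that both conditions share, such as sex, counts there as a genotype effect. The p-values for genotype thus measure how alike the 2 pairs are, not the spread among mice. Values for 1 pair of libraries have no replicate, so they describe these libraries and carry a 95% interval for counting error only. A count of 0 allows up to 3 counts, which is 0.0713 to 0.0884 CPM of a library's unscaled total. The words rose and fell are kept for genes with an adjusted p under 0.05 in the edgeR model. In simulated data, a larger share of such calls was false than that limit allows.

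The gene entries for miR-7 came first, since the series text states that the counts were used to find protein-coding genes lowered by this microRNA. Mir7-1, the entry for a miR-7 precursor, had 15, 10, 7 and 7 counts, too few for testing. It lies at 58392779 to 58392886 on chromosome 13 of GRCm38 (GENCODE M21, the gene with the same ID), inside an intron of Hnrnpk. Mir7-2 on chromosome 7 and Mir7b on chromosome 17 had 0 counts in every library, as had Cdr1, the gene on the strand opposite the circular RNA that binds miR-7, so that entry gives no value for the circular RNA. Mature microRNAs carry no poly(A) tail, so these counts did not measure miR-7 itself. Hnrnpk, which encodes an RNA-binding protein and hosts the precursor, stood at 227, 213, 229 and 183 CPM. Its genotype fit was log2 -0.11 ± 0.19, adjusted p 0.989, and its LPS fit was log2 -0.21 ± 0.19, adjusted p 0.425. The other tested member of the list of miR-7 loci and partners, the Oip5os1 noncoding RNA that directs miR-7 decay, had 99.6, 63.2, 108 and 42.2 CPM and fell with LPS (1 of 2 tested members fell, the same when adjusted over the list alone). Neither member passed the test for genotype.

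LPS raised inflammatory and interferon genes and lowered cell-cycle genes in both genotypes. Il6, which encodes a pyrogenic cytokine, rose from 3.46 to 369 CPM in wild-type and from 0.153 to 374 CPM in deficient macrophages (log2 8.23 ± 1.0, adjusted p 0.00181). Il12b, a subunit of cytokines that drive T cell responses, rose from 32.3 to 2448 CPM in wild-type and from 3.57 to 3329 CPM in deficient macrophages (log2 8.0 ± 1.03, adjusted p 0.00219). Nos2, the inducible nitric oxide synthase, rose from 93 to 7873 CPM in wild-type and from 3.77 to 2393 CPM in deficient macrophages (log2 7.81 ± 0.83). Clspn, needed for the replication checkpoint, fell from 15.1 to 0.151 CPM in wild-type and from 9.12 to 0.134 CPM in deficient macrophages (log2 -6.35 ± 0.44, adjusted p 0.000287). Of 12730 genes tested, 2297 rose and 2075 fell. Scaling by total counts moved the split to 1550 higher and 3840 lower, since it shifted the median log2 LPS effect of all genes by -0.44 in wild-type and -0.38 in deficient macrophages. A model with LPS alone gave 2090 higher and 1835 lower genes. In that model, leaving out the wild-type unstimulated library left 1051 higher and 640 lower, leaving out the wild-type LPS library 1451 and 1247, leaving out the deficient unstimulated library 1201 and 776, and leaving out the deficient LPS library 1744 and 1464. The third way to part the 4 libraries into pairs is the genotype by LPS term, tested here with genotype counted as spread. It gave 0 genes in edgeR, with 213 at an unadjusted p under 0.05. Genotype differences spread more widely than that term (standard deviation 0.56 against 0.34 over 8220 genes with a mean CPM of at least 10). Few calls were therefore possible, and the split is no null control for the LPS calls.

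**Figure D1:**
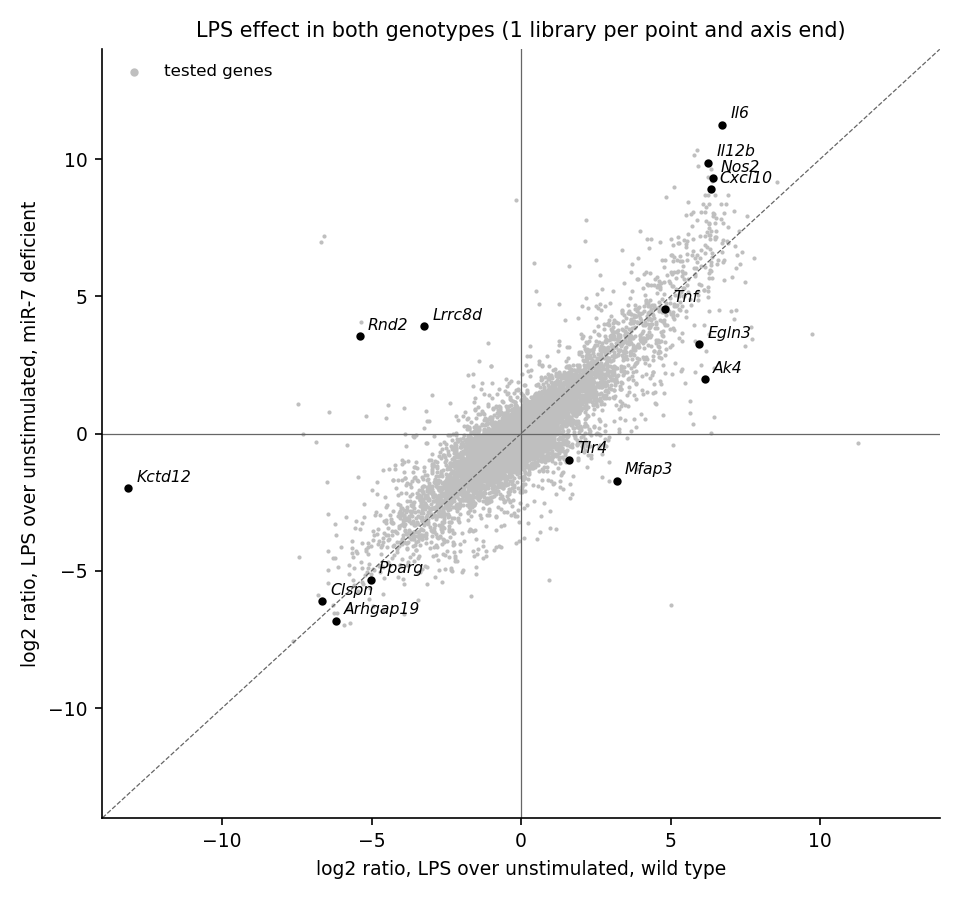
Log2 ratio of LPS to unstimulated CPM in the wild-type pair (horizontal) and the miR-7 deficient pair (vertical), 1 point per tested gene. The Pearson correlation across the 12730 genes was 0.831, and Rnd2, Lrrc8d, Mfap3 and Tlr4 lie in the quadrants of opposite sign.

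Among the genes with the highest fitted LPS effects, several were near silent without LPS. Zfp811, a zinc-finger gene, had 0 counts in both unstimulated libraries and was at least 156-fold higher with LPS in wild-type and at least 168-fold higher in deficient cells. Btla, an inhibitory receptor of lymphocytes and myeloid cells, was at least 158-fold and 72.6-fold higher. Ereg, a ligand of the epidermal growth factor receptor, rose from 4 and 0 counts to 32.2 and 44.3 CPM. Art3, an ADP-ribosyltransferase gene, rose from 0 and 4 counts to 7.15 and 26.8 CPM. Ereg and Art3 share exonic bases with other genes, so the assignment of their reads is uncertain. The chemokine Ccl5 rose from 64.9 to 5296 and 4.94 to 3913 CPM (log2 7.95 ± 0.94, adjusted p 0.00161). Ifit1bl1, of a family of interferon-induced RNA binders, rose from 10.6 to 1274 and 3.52 to 1451 CPM (log2 7.78 ± 0.54). Ptgs2, the inducible cyclooxygenase, rose from 31.1 to 2619 and 3.24 to 1896 CPM (log2 7.74 ± 0.80). Each of these calls held under the 4 alternatives tried for named genes.

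At the other end, Cd300ld5, a member of the CD300 family of leukocyte receptors, had 17.95 and 15.2 CPM without LPS and 0 counts with it, at least 198-fold and 189.97-fold lower. Arhgap19, a GTPase-activating protein of dividing cells, fell from 61.7 to 0.844 and 54.1 to 0.481 CPM (log2 -6.48 ± 0.30, adjusted p 0.000173). Npas4, an activity-induced transcription factor best known in neurons, fell from 13.5 to 0.121 and 12.6 to 0.214 CPM (log2 -6.26 ± 0.45). St6gal1, a sialyltransferase, fell from 80.2 to 0.905 and 82.7 to 2.67 CPM, and Adgre4, an adhesion receptor of macrophages, from 5.77 to 0.121 and 19.6 to 0.427 CPM. Slc27a6, a fatty acid transporter, fell from 20.5 to 0.121 and 21.2 to 0.935 CPM, and Ptger3, a prostaglandin receptor, from 10.4 to 0.332 and 8.33 to 0.107 CPM. Rnf150, a ubiquitin ligase gene, fell from 55.3 to 1.03 and 33.2 to 0.961 CPM, and Matk, a kinase that restrains Src family kinases, from 71.03 to 1.81 and 67.4 to 1.52 CPM (log2 -5.38 ± 0.25). St6gal1 and Rnf150 share exonic bases with other genes.

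Most tested members of the inflammatory lists rose with LPS. Of 22 cytokine genes, 19 rose, 0 fell and 3 did not pass the test (20 rose and 0 fell when adjusted over the list alone). Il1b and Il1a, the fever-inducing interleukins, rose from 73.1 to 5566 and 13 to 5406 CPM and from 67.1 to 5510.5 and 31.6 to 5189.7 CPM. Tnf, the cytokine tumour necrosis factor, rose from 19.8 to 557 and 42.4 to 994 CPM (log2 4.68 ± 0.23, adjusted p 0.000173). Il10, which restrains inflammation, rose from 0.427 CPM and 0 counts to 19.7 and 8.41 CPM. Of 20 chemokines, 16 rose, 0 fell and 4 did not pass the test (16 rose and 0 fell when adjusted over the list alone). Cxcl9 rose from 0.278 to 52.8 and 0.204 to 50.01 CPM, Cxcl10 from 11.8 to 958 and 2.91 to 1386 CPM and Ccl22 from 26.3 to 979.8 and 66.8 to 1696 CPM, while Ccl6, abundant throughout, did not pass (2384, 2861, 2502 and 2722 CPM). All 46 interferon-stimulated genes rose, 46 of them when adjusted over the list alone. The antiviral gene Rsad2 rose from 120.1 to 9408 and 36.4 to 7165 CPM, Ifit2 from 48.3 to 4336 and 31.2 to 4204 CPM, and the guanylate-binding protein gene Gbp5 from 19.2 to 1624 and 7.39 to 1961 CPM.

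Of 31 antimicrobial and inflammatory effector genes, 28 rose, 0 fell and 3 did not pass the test (29 rose and 0 fell when adjusted over the list alone). Acod1, which makes the antimicrobial metabolite itaconate, reached 11469 and 11256 CPM with LPS, from 179 and 263 CPM. Cybb, the catalytic subunit of the phagocyte oxidase, rose from 1613 to 4374 and 2688 to 4889.8 CPM. Of 24 NF-kB subunits and feedback regulators, 21 rose, 0 fell and 3 did not pass the test (22 rose and 0 fell when adjusted over the list alone). Socs1, an inhibitor of cytokine receptors, rose from 4.79 to 141 and 3.47 to 189 CPM, Socs3 from 16.01 to 300.1 and 15.4 to 279.9 CPM and the ubiquitin-editing enzyme Tnfaip3 from 44.9 to 863 and 66.2 to 849.98 CPM. Genes of the receptor pathway itself moved less. Of 27, 9 rose, 2 fell and 16 did not pass the test (9 rose and 2 fell when adjusted over the list alone). The co-receptor Cd14 rose from 97.7 to 908 and 89.8 to 971 CPM, Fos fell from 54.7 to 20.8 and 65.3 to 12.1 CPM, and the kinase Mapk3 did not pass (256, 192, 242 and 178 CPM). Of 12 inflammasome genes, 8 rose, 2 fell and 2 did not pass the test (9 rose and 2 fell when adjusted over the list alone). Casp4, the sensor of cytosolic LPS, rose from 12.6 to 225 and 16.2 to 168 CPM, Nlrp3 from 48.4 to 367 and 52.3 to 239 CPM, and Txnip, which shares exonic bases with another gene, fell from 477 to 67.4 and 309 to 135 CPM. Of 24 genes of antigen presentation, 17 rose, 1 fell and 6 did not pass the test (17 rose and 1 fell when adjusted over the list alone). Cd40, a co-stimulatory receptor, rose from 8.64 to 587 and 2.32 to 757 CPM, and the peptide transporter subunit Tap1 from 38.1 to 565 and 27.9 to 653 CPM. B2m rose from 3338 to 6653 and 3179 to 6219 CPM (adjusted p 0.0132), a call that ended when libraries were scaled by total counts.

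Division genes fell. Of 31 mitosis genes, 2 rose, 27 fell and 2 did not pass the test (2 rose and 27 fell when adjusted over the list alone). Kif23, a motor of the dividing spindle, fell from 15.01 to 1.90 and 8.08 to 0.694 CPM, and the checkpoint kinase Bub1b from 18.04 to 3.86 and 10.02 to 0.427 CPM. The risers were the proliferation marker Mki67, from 65.5 to 176 and 69.8 to 200.1 CPM, and the spindle factor Tpx2, from 16.6 to 42.6 and 18.7 to 34.6 CPM. Of 29 replication genes, 0 rose, 20 fell and 9 did not pass the test (0 rose and 22 fell when adjusted over the list alone), among them Rrm2, which makes DNA precursors, from 34.7 to 0.392 and 20.1 to 1.04 CPM, and the replication clamp Pcna, from 382 to 171 and 255 to 142 CPM. Of 38 genes typical of macrophages, 8 rose, 15 fell and 15 did not pass the test (8 rose and 18 fell when adjusted over the list alone). Lysozyme Lyz2 fell from 17670 to 8664 and 18594 to 10310 CPM, and the high-affinity antibody receptor Fcgr1 rose from 52.6 to 403 and 23.8 to 423 CPM. Of 18 genes of alternative activation, 6 rose, 7 fell and 5 did not pass the test (6 rose and 8 fell when adjusted over the list alone). Pparg, a lipid-sensing nuclear receptor, fell from 43.5 to 1.33 and 39.5 to 0.988 CPM, and Myc from 17.5 to 1.39 and 16.9 to 1.31 CPM. The fungal receptor Clec7a fell from 2157 to 1128 and 2502 to 989 CPM, and Klf4 from 49.9 to 21.8 and 34.6 to 22.6 CPM.

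Lipid genes mostly fell or stayed unpassed. Of 24 cholesterol synthesis genes, 0 rose, 12 fell and 12 did not pass the test (0 rose and 14 fell when adjusted over the list alone). Dhcr7, the last enzyme of one branch of the pathway, fell from 60.8 to 11.1 and 83.1 to 17.5 CPM, and Hmgcs1 from 179 to 97.4 and 371 to 170.4 CPM. Of 18 LXR targets and lipid handling genes, 2 rose, 7 fell and 9 did not pass the test (2 rose and 7 fell when adjusted over the list alone). The fatty acid binders Fabp4 and Fabp5 fell from 92.04 to 6.45 and 111 to 8.70 CPM and from 1921 to 301 and 1749.7 to 357 CPM. The cholesterol exporter Abca1 rose from 199 to 556 and 409 to 562 CPM (adjusted p 0.0423), a call that ended under total-count scaling and after 1.81% of the wild-type LPS counts was taken from the wild-type unstimulated library. Of 29 lysosome genes, 4 rose, 6 fell and 19 did not pass the test (4 rose and 9 fell when adjusted over the list alone). Tfeb, the master regulator of lysosome genes, fell from 69.2 to 10.4 and 68.1 to 13.1 CPM, and the proton pump subunit Atp6v0d2 from 1115 to 219 and 1179 to 212 CPM. Psap, the most abundant member, did not pass (19066, 13187, 17346 and 12914 CPM). Glycolysis and hypoxia-inducible genes went the other way: of 27, 21 rose, 0 fell and 6 did not pass the test (23 rose and 0 fell when adjusted over the list alone). Egln3, an oxygen-sensing hydroxylase, rose from 2.44 to 151 and 0.612 to 5.82 CPM, and the mitophagy gene Bnip3 from 13.1 to 283 and 13.6 to 38.2 CPM. Of 25 genes of the TCA cycle and oxidative phosphorylation, 1 rose, 3 fell and 21 did not pass the test (1 rose and 2 fell when adjusted over the list alone). Cycs, cytochrome c, rose from 51.7 to 167 and 57.6 to 171 CPM, fumarase Fh1 fell from 34.8 to 10.1 and 31.4 to 13.5 CPM, and the ATP synthase subunit Atp5b stood at 551, 556, 512 and 566 CPM. Of 22 antioxidant genes, 14 rose, 1 fell and 7 did not pass the test (15 rose and 2 fell when adjusted over the list alone). The heme-degrading enzyme Hmox1 rose from 393 to 5334 and 357 to 2561 CPM, the cystine importer Slc7a11 from 138 to 1698 and 352 to 1429 CPM, and the peroxidase Gpx1 fell from 267 to 50.7 and 367 to 76.3 CPM. Of 24 genes of the unfolded protein response, 5 rose, 3 fell and 16 did not pass the test (5 rose and 3 fell when adjusted over the list alone). Trib3 rose from 3.76 to 21.7 and 3.08 to 6.22 CPM, while the chaperone Calr did not pass (968, 1256, 679 and 935 CPM).

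**Figure D2:**
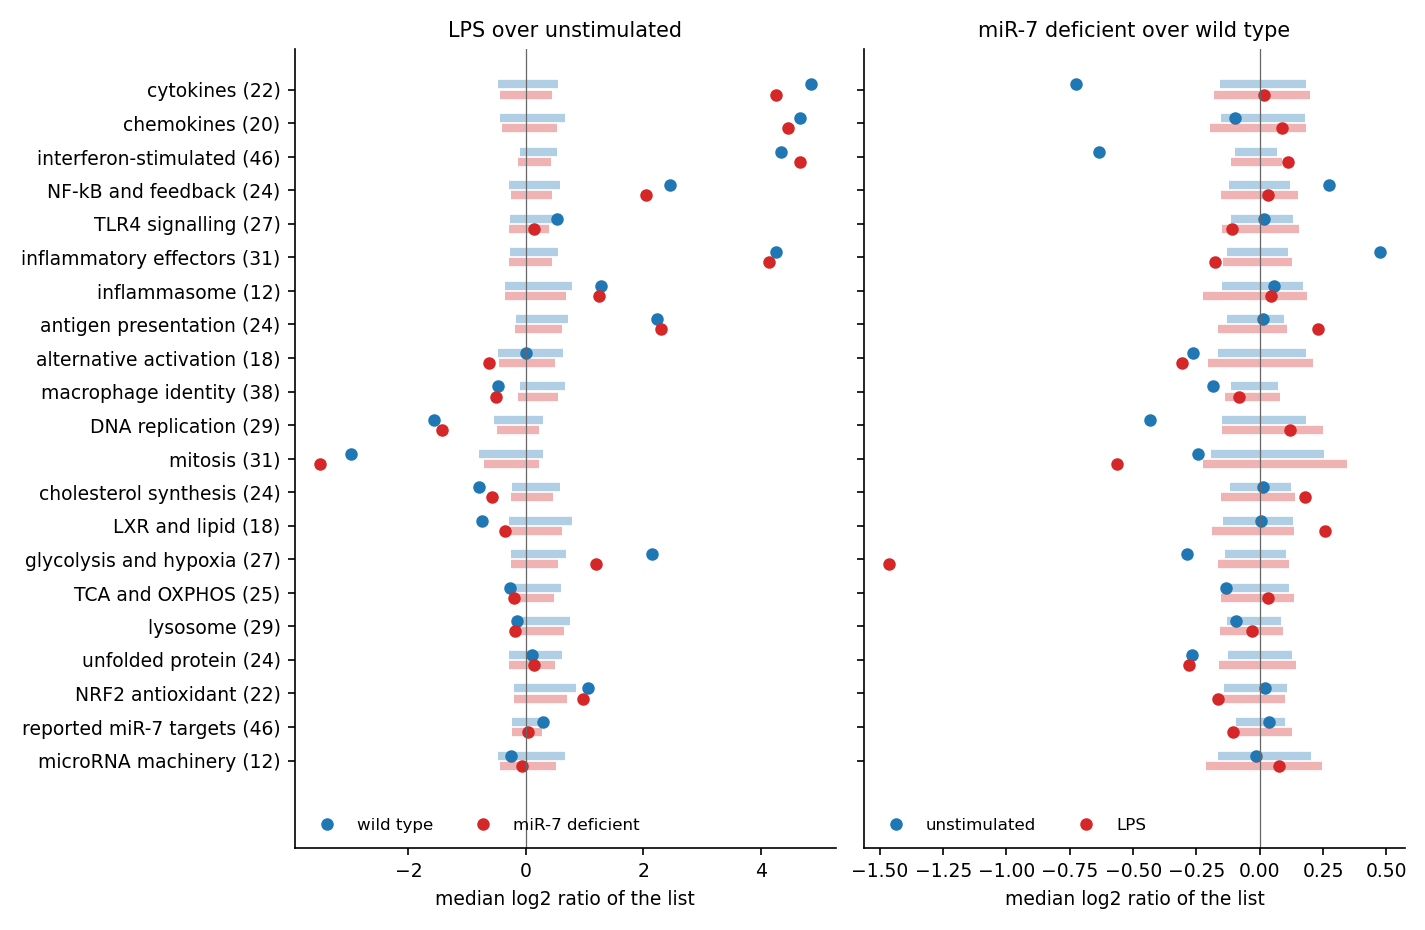
Median log2 ratio of the tested members of each gene list in each comparison of libraries, with bars for the central 95% of random lists matched on expression and the number of members tested. In the deficient over wild-type comparison with LPS, the glycolysis and hypoxia list has a median of -1.46.

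Within each genotype, the question was how strongly each pair of libraries answered LPS. In the wild-type pair, 1888 genes were higher and 1693 lower with LPS by an interval wholly beyond 2-fold. The deficient pair had 1588 and 1496 such genes. Of these, 1342 were higher in both pairs (236 if the pairs were independent), 1100 were lower in both (199) and 15 were opposite (433). Across genes, which are not replicates, the LPS effects of the pairs had a Pearson r of 0.831 and a Spearman rho of 0.799. Some genes answered in 1 pair far more than in the other. Il33, an alarm cytokine, was at least 214-fold higher in wild-type cells, from 0 counts, and 10.8-fold higher in deficient cells. Stat4, a signal transducer of interleukin receptors, was at least 180.1-fold and 45.8-fold higher. Schip1, a cytoskeletal adaptor gene, had 1 count in the wild-type unstimulated library, and its log2 ratios were 9.73 (7.24 to 15.03) and 3.62 (3.17 to 4.10). Il6 was 106-fold higher in the wild-type and 2446-fold higher in the deficient pair, and Apol9b, an interferon-induced apolipoprotein gene, 59.8-fold and at least 867-fold. After 1.81% of the wild-type LPS counts was taken from the wild-type unstimulated library, nothing was left there of Il6 and Schip1, so the contrast for Il6 had no value.

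Genes lower with LPS also differed between pairs. Kctd12, a membrane receptor subunit gene, went from 814 CPM to 0 counts in wild-type cells, at least 8996-fold lower, and from 869.8 to 221 CPM in deficient cells. Cd300ld4, another CD300 receptor, went from 7.99 CPM to 0 counts in wild-type and from 6.30 to 0.828 CPM in deficient cells. Sla2, an adaptor that restrains antigen receptors, had 26.6, 0.151, 22.4 and 47.7 CPM. Others reached 0 counts in both LPS libraries. Rasgrp3, a Ras activator, was at least 88.1-fold and 43.9-fold lower. The endothelial transcription factor gene Sox7 was at least 52.9-fold and 118-fold lower, and the organic anion transporter Slco2b1 at least 76.8-fold and 93.6-fold. Clec4b1, a lectin receptor, was 15.2-fold lower in wild-type and at least 95.5-fold lower in deficient cells. Kctd12, Sla2, Schip1, Stat4 and Slco2b1 share exonic bases with other genes.

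The genotype comparison addressed the stated aim of the series, genes lowered by miR-7, which would be higher without it. Sex-linked genes stood far apart. Xist, the RNA that silences an X chromosome in females, had 0.513 CPM in wild-type against 714 CPM in deficient cells without LPS, and 0.483 against 686 CPM with LPS (log2 10.45 ± 0.29, adjusted p 0.000262). Eif2s3y, Ddx3y, Kdm5d and Uty on the Y chromosome had 41.2, 43.03, 22.1 and 11.3 CPM in the wild-type unstimulated library, and at most 12 counts in either deficient library. Of the 5 sex markers, 1 was higher and 4 were lower in the deficient libraries, the same when adjusted over the list alone. The labels give no sex, but these values mark the wild-type cells as male and the deficient cells as female, so sex is confounded with genotype. Over all genes tested, 49 were higher and 21 lower, with 968 at an unadjusted p under 0.05. Without genes on X and Y and pseudogenes, 21 were higher and 13 lower. The higher count was 27 with DESeq2 size factors, 31 with total counts, 18 without a filter and 147 by DESeq2's own test, where the lower count was 12 without a filter and 81 by DESeq2. When LPS was left out of the model, edgeR gave 0 in either direction, with 187 at an unadjusted p under 0.05. Leaving out each library from that model also gave 0, with 100 to 200 at an unadjusted p under 0.05.

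Beside Xist, its antisense gene Tsix had 0 counts in wild-type cells and was at least 534-fold and 385-fold higher in deficient cells without and with LPS. Entries of ferritin light chain copies stood out. How reads shared by such copies were handled is not stated, so these counts may not measure expression of the copies themselves. Ftl1-ps2 had 0.128 against 74.99 CPM unstimulated and 0.121 against 59.01 CPM with LPS (log2 9.05 ± 0.32, adjusted p 0.000424), Ftl2-ps 19.8 against 1948 CPM unstimulated and 15.6 against 1568 CPM with LPS, and Ftl1-ps1 39.8 against 493 CPM unstimulated and 30.6 against 436 CPM with LPS. Ftl1, which encodes the iron-storage subunit itself, did not pass and was lower in the deficient libraries (9512 against 6328 CPM unstimulated and 7563 against 5287 CPM with LPS). Chil1, a secreted chitinase-like protein of activated macrophages, had 0 and 8 counts in wild-type cells and 5.45 and 102 CPM in deficient cells (adjusted p 0.000980). Cacna1a, a neuronal calcium channel subunit gene, had 0.705 against 128 CPM unstimulated and 0.121 against 32.5 CPM with LPS (log2 7.65 ± 0.31, adjusted p 0.000489). Fam177a had 10 and 0 counts in wild-type cells and 29.4 and 79.5 CPM in deficient cells (adjusted p 0.0181). The histone pseudogene Hist1h2al had 0.171 against 4.36 CPM unstimulated and 0.151 against 5.26 CPM with LPS, and the microRNA entry Mir692-2 0.214 against 46.5 CPM unstimulated and 0.151 against 184 CPM with LPS. Of these, only Fam177a and Chil1 share no exonic bases with another gene.

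Among genes lower in both deficient libraries, Ear6, an eosinophil-type ribonuclease gene, had 38.1 and 39.1 CPM in wild-type cells and 0 and 13 counts in deficient cells (adjusted p 0.0167). Nlrp1a, an inflammasome sensor, had 14.3 and 4.52 CPM in wild-type cells and 0 counts in deficient cells, at least 186-fold and 56.5-fold lower. Glrp1, a glutamine repeat protein gene, had 0 counts in deficient cells and was at least 30.2-fold and 278-fold lower. Arg1, the arginase of alternatively activated macrophages, had 1.03 and 11.4 CPM in wild-type cells and 0 and 4 counts in deficient cells (adjusted p 0.0185). Cyp4f18, which degrades leukotriene, had 28.7 against 0.816 CPM unstimulated and 19.4 against 0 CPM with LPS and did not pass (adjusted p 0.0520). Chil3, another chitinase-like protein, had 2582 against 727 CPM unstimulated and 2327 against 465 CPM with LPS (log2 -2.08 ± 0.23, adjusted p 0.0256).

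**Figure D3:**
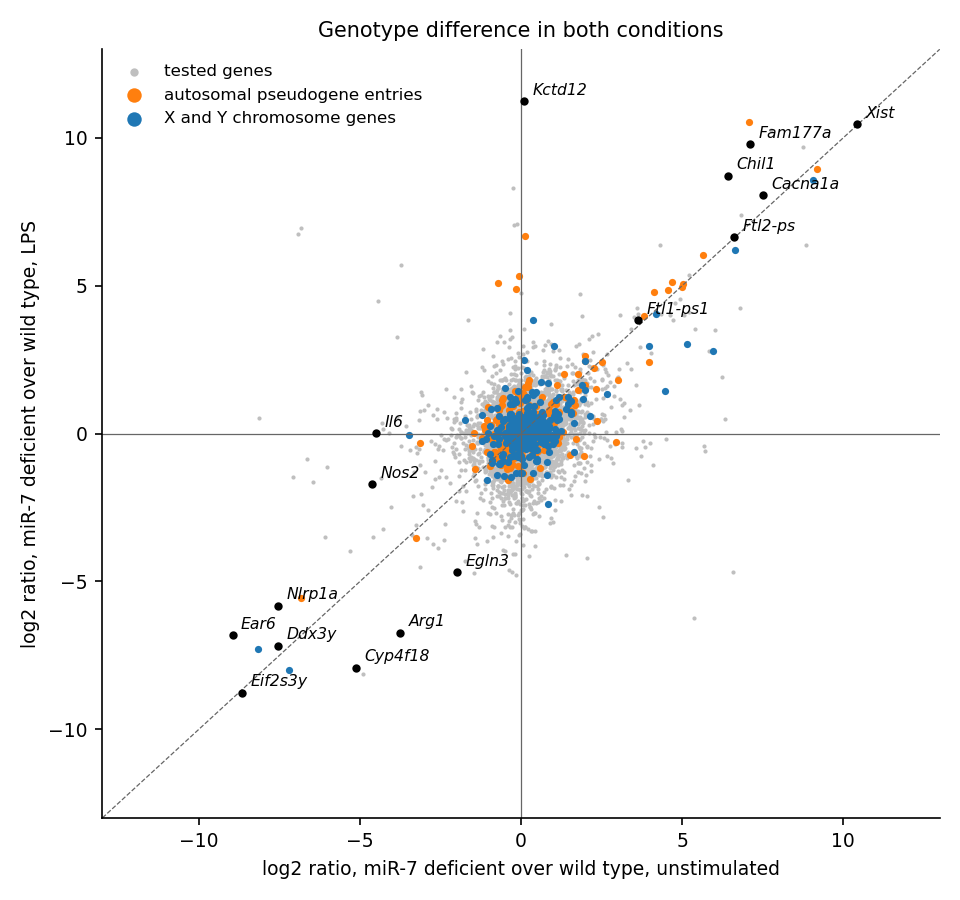
Log2 ratio of deficient to wild-type CPM without LPS (horizontal) and with LPS (vertical), 1 point per tested gene, with genes on X and Y in blue and autosomal pseudogenes in orange. By an interval wholly beyond 2-fold, 127 genes are higher and 53 lower in both conditions.

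Within each condition, 359 genes were higher and 179 lower in the deficient unstimulated library by an interval wholly beyond 2-fold, and 329 were higher and 387 lower with LPS. Of these, 127 were higher in both conditions (9.28 if independent), 53 were lower in both (5.44) and 26 were opposite (15.5). Pseudogene entries made up 29 of the higher genes in each condition, and 3 and 7 of the lower ones. Across all tested genes the differences of the 2 conditions had a Pearson r of 0.358 and a Spearman rho of 0.137. The Pearson r was 0.276 without genes on X and Y and pseudogenes. Over the 8220 genes with a mean CPM of at least 10, the standard deviation of log2 values was 1.39 for LPS, 0.56 for genotype and 0.34 for their interaction, against 0.07 for counting error. In 1 condition alone, Hist2h2aa1, a histone gene that shares exonic bases with another, had 21.7 CPM in the wild-type and 0 counts in the deficient unstimulated library, with 19.2 and 27.8 CPM under LPS. Kctd12 was at least 2445-fold higher in the deficient LPS library, from 0 counts in wild type.

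In the unstimulated libraries, interferon and cytokine genes were lower in deficient than in wild-type cells. The list medians were -0.63 (log2, 46 interferon-stimulated genes) and -0.73 (22 cytokine genes), below all matched random lists. Il6 was -4.50 (-5.97 to -3.35), Il12b -3.18 (-3.44 to -2.93), Il1b -2.49 (-2.63 to -2.36), Ccl5 -3.71 (-3.93 to -3.50), Nos2 -4.62 (-4.87 to -4.39) and Cxcl10 -2.02 (-2.32 to -1.72). Those values rest on the wild-type unstimulated library, which held a median of 1.81% of the wild-type LPS counts for 53 genes that LPS raised at least 100-fold in the deficient pair (quartiles 1.58% and 2.36%). The deficient unstimulated library held 0.426% of the deficient LPS counts for the same genes, a share that the choice of genes keeps low. In an alternative, 1.81% of the wild-type LPS counts was subtracted from the wild-type unstimulated library. The interferon median became 0.24, the cytokine median 0.02, Il1b 2.90 and Il12b 1.93. Nothing was left of Il6, Ccl5, Nos2 and Cxcl10 in that library, so their differences had no value. Il1b and Il12b stood at 1.85% and 1.86% there before, so their values rest on small remainders. The share came from induced genes such as these, and no other share was tried. Over members with a CPM of 10 or more, the cytokine median was -0.31. Not all inflammatory genes were lower. Tnf was 1.10 (0.99 to 1.22), Ccl22 1.34 (1.24 to 1.44), the NF-kB inhibitor Nfkbie 2.10 (1.97 to 2.23) and Icam1, an adhesion molecule, 1.23 (1.17 to 1.29). The effector list had a median of 0.48 (above all matched random lists) and the feedback list of 0.27 (percentile 99.99). Mmp9, a matrix protease, was 4.50 (3.66 to 5.47). The chemokine median was -0.10 (percentile 12.3), became 1.36 after the subtraction and was -0.39 over members with a CPM of 10 or more.

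**Figure D4:**
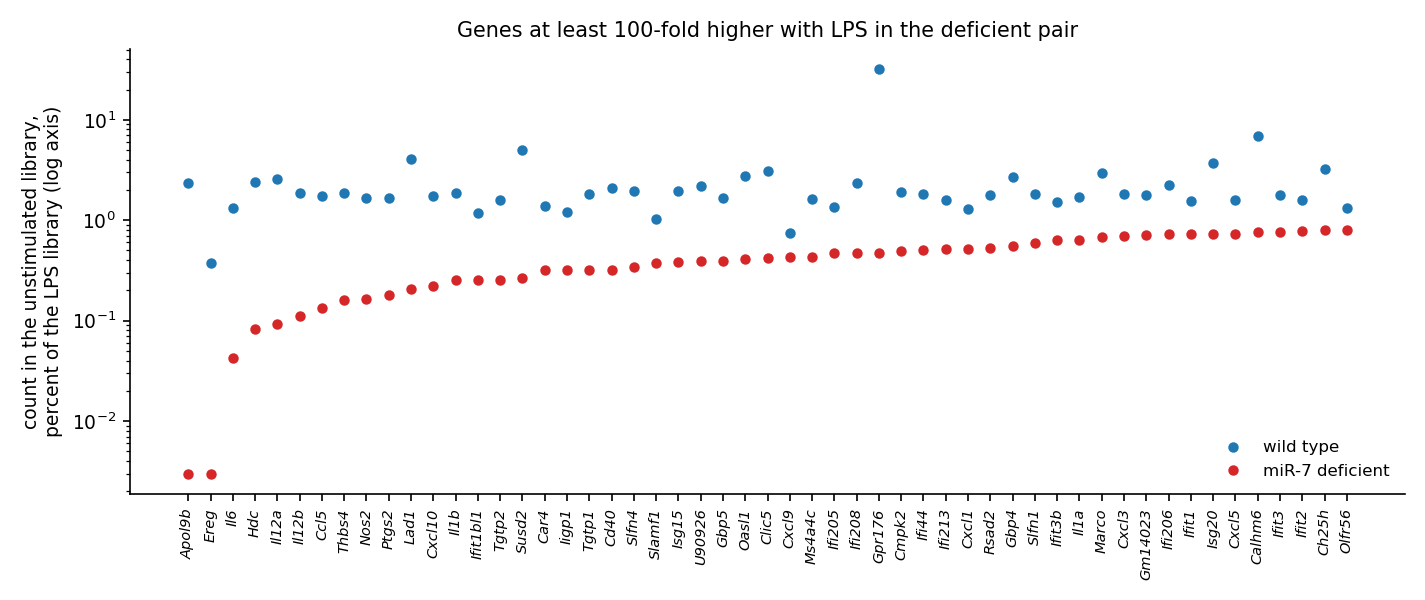
Count in the unstimulated library as a percentage of the count in the LPS library (log axis), for the 53 genes raised at least 100-fold in the deficient pair, in each genotype. The medians are 1.81% in wild-type and 0.426% in deficient macrophages.

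Other lists also lay outside random lists without LPS. Replication genes had a median of -0.43 (percentile 0), with Mcm6 at -1.0 (-1.10 to -0.91) and Pcna at -0.58 (-0.62 to -0.55), while Fen1 was higher at 0.57 (0.46 to 0.69). Mitosis genes had a median of -0.25 (percentile 0.780), and Bub1b was -0.85 (-1.03 to -0.67). Genes typical of macrophages had a median of -0.18 (percentile 0.0200), and the integrin Itgam was -1.73 (-1.76 to -1.70). The unfolded protein response list had -0.27 (percentile 0), with Calr at -0.51 (-0.53 to -0.49). Alternative activation genes had -0.26 (percentile 0.120), with Chil3 at -1.83 (-1.85 to -1.81) and the lectin Mgl2 at -0.97 (-1.08 to -0.86). Oxidative phosphorylation genes had -0.13 (percentile 1.15, and 3.56 among random lists not matched on expression). Antigen presentation (0.01), TLR pathway (0.02), inflammasome (0.06), cholesterol (0.01), LXR (0.00), antioxidant (0.02), lysosome (-0.09) and microRNA machinery (-0.01) medians lay within the central 95% of random lists. Within them, H2-Eb1, a class II antigen-presenting chain, was 1.05 (1.03 to 1.07) and Hmgcs1 1.05 (1.01 to 1.09).

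With LPS, glycolysis and hypoxia-inducible genes were lower in the deficient library. The median of 27 members was -1.46 against -0.29 without LPS, below all matched random lists in both conditions, and 2 of 27 lay above 0 with LPS. After the subtraction from the wild-type unstimulated library, the median without LPS was -0.11, inside the range of random lists (-0.14 to 0.10), and the median with LPS was -1.47. Adm, a vasodilator peptide induced by low oxygen, had 33.1 CPM in wild-type and 1.68 CPM in deficient LPS cells, and 12 and 0 counts without LPS. It was the 1 member lower by the test (log2 -4.37 ± 0.45, adjusted p 0.0213), against 3 when adjusted over the list alone, and its adjusted p was 0.0947 after the wild-type subtraction. Egln3 was -4.69 (-4.90 to -4.50) with LPS, the collagen hydroxylase P4ha2 -3.48 (-3.70 to -3.26) and Bnip3 -2.89 (-2.97 to -2.81). The glycolytic enzymes pyruvate kinase Pkm, at -0.82 (-0.83 to -0.80), and aldolase Aldoa, at -0.52 (-0.54 to -0.51), differed less than these genes. Ak4, a mitochondrial adenylate kinase also induced by hypoxia, had 1.05, 73.6, 4.31 and 17.1 CPM, and Hmox1 was -1.06 (-1.07 to -1.05).

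**Figure D5:**
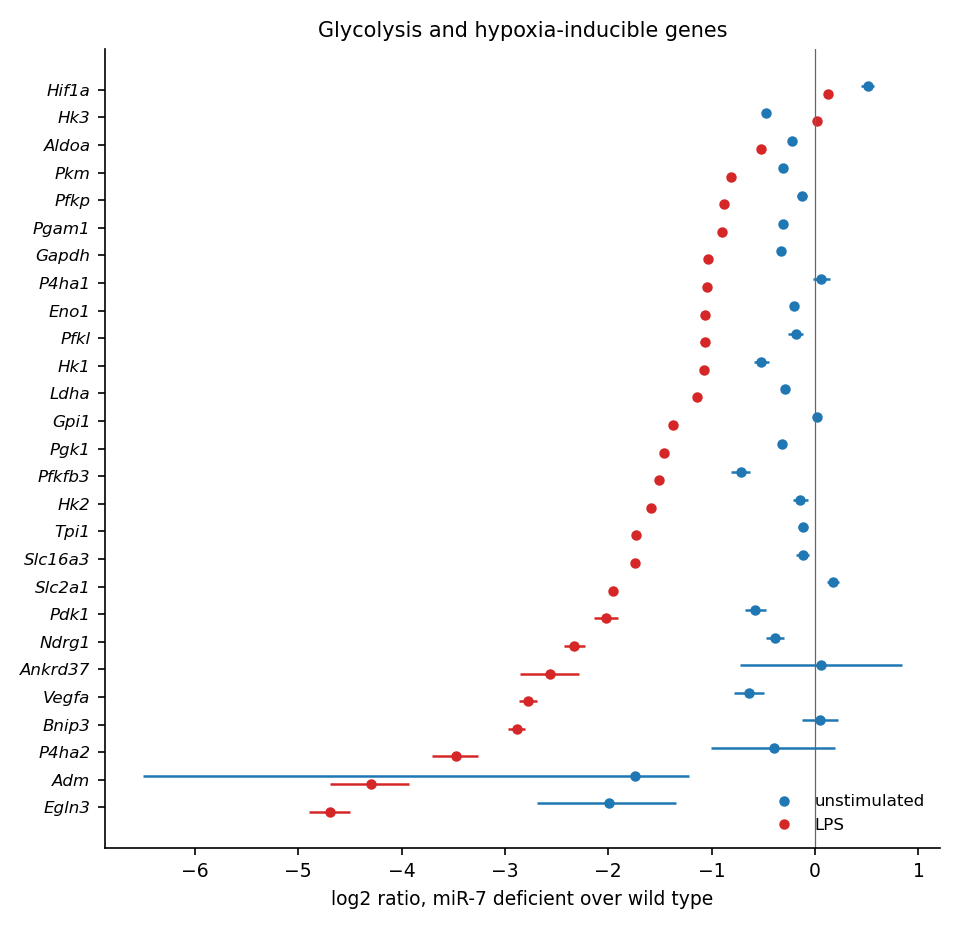
Log2 ratio of deficient to wild-type CPM for each of the 27 glycolysis and hypoxia-inducible genes, without LPS (blue) and with LPS (red), with 95% counting intervals. With LPS, 25 of the 27 genes lie below 0.

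With LPS, the cytokine and chemokine medians lay within random lists, at 0.02 (percentile 54.6) and 0.09 (percentile 82.9), and the interferon median was 0.11 (percentile 99.1, and 89.5 among unmatched lists). Il6 was 0.02 (-0.01 to 0.06), Il1b -0.04 (-0.05 to -0.03), Acod1 -0.03 (-0.03 to -0.02) and Ifit2 -0.04 (-0.05 to -0.03). Other genes were further apart. Il10 was -1.23 (-1.43 to -1.03), Nos2 -1.72 (-1.73 to -1.71), Tlr4 -2.87 (-3.08 to -2.67) and the stress cytokine Gdf15 -2.96 (-3.35 to -2.59), while Tnf was 0.84 (0.81 to 0.86), Il12b 0.44 (0.43 to 0.46), Cxcl10 0.53 (0.51 to 0.55) and Il12a 1.32 (1.23 to 1.40). Slfn8, a Schlafen family gene, was the 1 interferon-stimulated gene lower by the test (log2 -3.26 ± 0.35, adjusted p 0.0244), and adjusted over the list alone 1 was higher and 1 lower. Its adjusted p was 0.160 after the subtraction from the wild-type unstimulated library. Xaf1, a pro-apoptotic interferon target, had 8.85 against 21.2 CPM unstimulated and 217 against 524 CPM with LPS (adjusted p 0.0667 over all genes). Antigen presentation genes had a median of 0.23 (percentile 99.99), LXR targets of 0.26 (percentile 99.95) and cholesterol genes of 0.18 (percentile 99.4, and 93.8 among unmatched lists). Dendritic markers summed to 242 against 512 CPM, carried by Ccr7 and Fscn1, but their median of 0.38 lay within random lists (percentile 88.5) and 0 of 7 passed for genotype in edgeR. Mitosis genes had -0.56, below all matched random lists (-0.25 over members with a CPM of 10 or more), with Bub1b at -3.18 (-4.03 to -2.42), and the unfolded protein response -0.28 (percentile 0.0200). Alternative activation genes had -0.31 (percentile 0.410) and effectors -0.18 (percentile 1.05).

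By the additive test for genotype, the fixed lists held few calls. Alternative activation had 0 higher and 2 lower members, Arg1 and Chil3 (3 lower when adjusted over the list alone), and Chil3's adjusted p was 0.0837 after the subtraction. The effector list had 1 lower, the same when adjusted over the list alone. Cytokines and chemokines had 0 in edgeR over all genes, and adjusted over the list alone each had 1 higher and 1 lower. Antigen presentation had 0, and adjusted over the list alone 1 higher. The feedback, TLR pathway, inflammasome, macrophage, replication, mitosis, cholesterol, LXR, oxidative phosphorylation, lysosome, unfolded protein, antioxidant, miR-7 target, miR-7 loci and microRNA machinery lists had 0 either way. Relb, an NF-kB subunit, came to log2 0.99 ± 0.22, adjusted p 0.222, and Tnf to log2 0.97 ± 0.20, adjusted p 0.192.

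The difference between the LPS effects of the 2 genotypes asked whether the response changed without miR-7. Beside both main effects, it left no degree of freedom for a test. By an interval wholly beyond 2-fold, 288 genes had a higher and 486 a lower LPS effect in deficient cells. Rnd2, a small GTPase gene, was 42.2-fold lower with LPS in wild-type and 11.7-fold higher in deficient cells, with 97.9, 2.32, 4.46 and 52.1 CPM. Lrrc8d, a volume-regulated channel subunit gene, had 154, 16.3, 10.6 and 159 CPM. Both share exonic bases with other genes, as do Kctd12 and Sla2, whose LPS effects were also higher in deficient cells. In the other direction, Mfap3, a fibril-associated protein gene, had 9.85, 90.5, 52.7 and 16.1 CPM, and the antisense entry Slfn5os 2.31, 123, 13.6 and 17.4 CPM. Tnc, an extracellular matrix gene, went from 0.406 to 20.3 and 4.03 to 6.76 CPM, and F3, tissue factor of blood clotting, from 2.65 to 20.2 and 9.89 to 4.83 CPM. Tlr4, the LPS receptor, was 1.61 (1.48 to 1.75) with LPS in wild-type and -0.95 (-1.19 to -0.72) in deficient cells. Among the lists, glycolysis and hypoxia genes had a median difference of -1.10, effectors of -0.58 and feedback genes of -0.41 (percentile 0.0200), while interferon genes had 0.66 and replication genes 0.51. The cytokine difference of 0.33, the chemokine difference of 0.23 and the interferon difference turned to -0.48, -1.36 and -0.17 when 1.81% of the wild-type LPS counts was taken from the wild-type unstimulated library. The effector difference became -1.15. The same subtraction turned Il12b from 3.62 to -1.48, Il1b from 2.45 to -2.94, Cd40 from 2.26 to -0.66 and Slfn4 from 2.07 to -1.85. Before it, their wild-type unstimulated counts were 1.86%, 1.85%, 2.07% and 1.93% of the wild-type LPS counts, close to the share removed. The turned values thus rest on small remainders, carry no interval and depend on the share chosen.

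Genes reported as direct targets of miR-7 were not higher as a group in the deficient libraries. Of 46 measured, the median was 0.04 without LPS (percentile 77.6) and -0.11 with LPS (percentile 2.89), and 0 passed the edgeR test for genotype. The insulin receptor substrate Irs2 was 0.20 (0.09 to 0.31) without LPS and -0.49 (-0.64 to -0.34) with LPS, the growth factor receptor Egfr 0.48 (0.14 to 0.82) and -0.59 (-0.90 to -0.28), and the NF-kB subunit Rela 0.27 (0.19 to 0.34) and 0.15 (0.09 to 0.21). Klf4 was -0.53 (-0.62 to -0.43) and 0.05 (-0.09 to 0.20), and Nlrp3 0.11 (0.02 to 0.20) and -0.62 (-0.66 to -0.58). With LPS, 12 of the list rose, 11 fell and 23 did not pass (13 and 12 when adjusted over the list alone), among them the amino acid transporter subunit Slc3a2, from 224 to 809 and 277 to 740.3 CPM. In the microRNA machinery, 2 of 12 rose, 1 fell and 9 did not pass, the same when adjusted over the list alone. Ago3 rose from 33.6 to 173 and 34.3 to 101 CPM, Ago4 fell from 27.3 to 6.57 and 28.1 to 8.20 CPM, and Dicer1 stood at 59.6, 35.98, 59.4 and 46.3 CPM.

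Loss of a microRNA leaves transcripts with its seed sites higher. Of 11303 tested genes with an annotated 3′ UTR, 517 held GTCTTCCA, the longest match to the miR-7 seed, 1229 held GTCTTCC without it and 1481 TCTTCCA alone. Genes with GTCTTCCA had a median deficient over wild-type log2 ratio of 0.01 without LPS, at percentile 1.43 of random lists matched on expression and UTR length, and of -0.01 with LPS, at percentile 45.0. Genes with GTCTTCC lay at 0.02 (percentile 7.40) and -0.01 (12.5), and those with TCTTCCA at 0.04 (75.7) and 0.01 (82.0). Matching on expression alone moved the percentile of GTCTTCCA genes to 63.7 without LPS, that of GTCTTCC genes to 99.3 without LPS and 0.680 with LPS, and that of TCTTCCA genes without LPS to 100. Of 139 other 7-mers with the same bases, 68 had a shift at least as high as GTCTTCC without LPS and 127 with LPS. Among 83 genes higher in both conditions with a searched UTR, 11 held GTCTTCC or GTCTTCCA (13.3%, against 15.4% of all searched genes).

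Marker lists of other cell types were low or carried by a few genes. Neutrophil markers summed to 925, 408, 769 and 215 CPM, of which the collagenase Mmp8 gave 917, 398, 761 and 204 CPM, and 2 of 3 tested fell with LPS. Dendritic markers summed to 42.6, 242, 48.1 and 512 CPM. There, 4 of 7 rose, among them the homing receptor Ccr7, from 4.40 to 148 and 4.08 to 316 CPM, and Fscn1, from 2.89 to 80.1 and 2.70 to 182 CPM, and 2 fell, among them Clec9a, from 23.1 to 4.34 and 29.8 to 1.31 CPM. Monocyte markers summed to 38.5, 109, 40.9 and 157 CPM (1 of 3 rose and 1 fell, Ly6c2 from 13.1 to 105 and 10.6 to 149.6 CPM and Ccr2 from 23.7 to 1.09 and 24.3 to 1.87 CPM). Osteoclast markers came to 426, 572, 554 and 545 CPM (1 of 6 rose and 2 fell), and endothelial ones to 434, 317, 453 and 447 CPM (1 of 3 rose, Kdr, and 1 fell, Vwf). B and plasma cell markers came to 65.04, 13.5, 81.9 and 20.7 CPM, mainly Cd22, which fell from 64.8 to 13.4 and 81.6 to 20.1 CPM. Eosinophil markers came to 76.03, 28.2, 109 and 44.2 CPM (1 of 2 fell, Siglecf), T and NK cell markers to 3.91, 3.17, 4.72 and 4.83 CPM (1 of 2 rose, Lck, a call that ended under total-count scaling, and 1 fell), and progenitor markers to 12.4, 6.30, 16.5 and 4.005 CPM (2 of 3 fell). Megakaryocyte markers came to 18.4, 22.4, 16.03 and 21.3 CPM, with 0 of 3 passing in edgeR. Fibroblast markers came to 6.24, 20.03, 7.77 and 21.8 CPM (1 of 2 rose, Pdgfrb), and mast cell and basophil markers to 4.66, 14.3, 4.996 and 3.23 CPM (1 of 2 rose, Cpa3). Erythroid markers came to 0.321, 2.38, 0.127 and 0.107 CPM, with none tested. Adjusted over the list alone, 1 more marker rose in each of the neutrophil, dendritic and osteoclast lists, 1 more fell in each of the fibroblast, progenitor and monocyte lists, and the other counts stayed. Sex markers summed to 118, 126, 714 and 687 CPM, and 0 of 5 passed for LPS. For genotype, adjusted over the list alone, 1 monocyte marker was higher and 1 mast cell marker, Cpa3, was lower, while over all genes only the sex markers passed.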

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

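The tests of low-level activation, of sex, of pseudogene reads and of a weaker LPS response were chosen only after the result was seen. The other tests below were chosen before it, apart from the share of seed sites among the higher genes. That comparison was not among the tests fixed beforehand.

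For 19 of the named genes, LPS moved the wild-type and the deficient pair in opposite directions, each by an interval that excludes 0. With 1 library per group the difference was not tested. Values are log2 LPS effects in wild-type and deficient cells, then their difference, deficient over wild type. In 8 genes the effect was higher in deficient cells. Rnd2 went from -5.40 to 3.55 (difference 8.93), Lrrc8d from -3.24 to 3.91 (7.14), Sla2 from -7.46 to 1.09 (8.42), Nek7 from -1.32 to 1.83 (3.14) and the antioxidant response gene Osgin1 from -1.60 to 2.17 (3.77). Hist2h2aa1 (-0.17 and 8.51, difference 11.27) and Fam177a (-1.24 and 1.43, difference 5.33) each had a library with 0 counts, so their differences depend on the 0.5 counts added and are no bound. Ear2, an eosinophil-type ribonuclease gene, had the smallest upward difference of these, from -0.45 to 0.18 (0.62). Sla2, Hist2h2aa1, Rnd2, Lrrc8d and Nek7 share exonic bases with another gene, so their reads may be split differently between libraries; genes that share exonic bases made up 40.6% of those tested, and leaving them out took the count of genes with a higher LPS effect in deficient cells from 288 to 162.

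In the other genes the LPS effect was lower in deficient cells. Tlr4, the LPS receptor, went from 1.61 to -0.95 (difference -2.56) and Mfap3 from 3.20 to -1.71 (-4.91). The protease Mmp9 went from 2.93 to -1.74 (-4.62) and tissue factor F3 from 2.93 to -1.03 (-3.96). Gdf15 went from 0.65 to -0.87 (-1.51), Mgl2 from 0.15 to -1.18 (-1.33), the platelet chemokine Ppbp from 1.26 to -0.86 (-2.11) and the transcription factor Gata2 from 0.93 to -0.90 (-1.83). The osteoclast markers Dcstamp and Ctsk went from 1.04 to -0.30 (-1.34) and from 0.25 to -0.47 (-0.72), and the TCA cycle enzyme Sucla2 from 0.38 to -0.23 (-0.61).

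LPS-induced genes stood at a low and even level in the wild-type unstimulated library, a median of 1.81% of their wild-type LPS counts over 53 genes, against 0.426% in the deficient pair, where the choice of genes raised at least 100-fold keeps it low. Low-level activation with gene-specific strength would spread these ratios about as widely as in the deficient pair, but their interquartile range was 0.58 against 1.31 on the log2 scale, and 0.31 against 1.08 over the 37 genes with at least 20 counts in both unstimulated libraries, where counting noise is small. That argues against gene-specific strength, not against an even weak stimulation. If material of the wild-type LPS library had entered the wild-type unstimulated one, under 5% of genes abundant under LPS would have an upper counting bound of this ratio below 0.904%. It was so for 1 of 5602 (0.0179%), and 4 lay below by the ratio itself, among them Cxcl9 (0.742%) and Ereg (0.375%). The deficient pair, without the even level, also stayed under that limit (48 of 5746, 0.835%), since few abundant genes are raised so strongly, so the test decides nothing. Mixing of the libraries or cells and an even weak stimulation both stay open.

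Between genotypes, 180 genes were apart in the same direction in both conditions. By Xist, Eif2s3y, Ddx3y, Kdm5d and Uty, the wild-type cells were male and the deficient cells female. Sex thus accounts for these genes and may account for others of the 11 genes on X and 6 on Y, together 9.44% of the set. Autosomal genes that differ by sex were not tested, so sex stays open for the rest. Of the Y entries, 2 were higher in the deficient libraries, against the direction of the other 4: Mid1-ps1 (3.98 and 2.95), looked up after its values were seen, and an entry with a provisional name. Pseudogene entries were 12.8% of the set against 3.21% of tested genes (Fisher's exact test, two-sided p 1.51e-08). Reads shared between other paralogs were not measured and stay open. Genes with 8mer seed sites of miR-7 lay at percentile 45.0 of matched lists with LPS and at 1.43 without. Those medians cover all 517 genes with such sites, so they do not speak on the set itself. Of 83 genes of the set that were higher and had a searched UTR, 13.3% held GTCTTCC or GTCTTCCA, against 15.4% of all searched genes. That argues against loss of repression at such sites as the cause for most of these higher genes. Of 163 autosomal members, 36.2% had another member among the 5 tested genes on either side, against 6.13% to 19.6% in random sets. Strain segments that differ between the mice may thus explain part of it, but neighbouring paralogs, which could share reads, were not set apart. Sex and strain are confounded with genotype in this design.

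Glycolysis and hypoxia-inducible genes were lower in the deficient LPS library, with a median of -1.46. For a weaker LPS response as a whole, 925 other genes raised at least 4-fold by LPS had a median deficient over wild-type log2 ratio of 0.0154. The LPS test counts a difference between genotypes as spread, which favours genes with like responses, so this median alone decides little. Lists fixed beforehand had medians with LPS of 0.02 (cytokines), 0.09 (chemokines), 0.11 (interferon-stimulated genes) and -0.18 (effectors). These lists were thus not lowered to the extent of the glycolysis and hypoxia list. Reads split between overlapping genes are argued against by the 14 members that share no exonic bases, whose median was -1.55. Culture density, oxygen, sex, strain and miR-7 itself were not tested and stay open, since each is confounded with the single deficient LPS library. A lower hypoxia-type response of that culture may be a biological difference, but with 1 library it cannot be separated from the culture.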

How the results depend on the processing

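The alternatives without genes that share exonic bases, without genes on X and Y and pseudogenes, with list members that share no exonic bases, with subtraction from the wild-type unstimulated library, and with genotype alone and 1 library left out were chosen after seeing the data. The additive model pairs libraries by genotype and by treatment only. No analysis paired by mouse or culture was possible, because each group held 1 library and nothing else in the labels links libraries. Depth limits low genes: a count of 0 allows up to 3 counts.

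Of 1824 fitted values of named genes, 1775 kept their side of the test, 26 passed only under total counts and 23 ceased to pass under an alternative. A change of sign in a fit that did not pass was not counted. Of 525 list medians 43 moved and 5 reversed. A median within random lists before was not counted as reversed when its sign changed. The median of reported miR-7 targets without LPS, for example, went from 0.035 to -0.0025 with size factors. Of 504 counts of list members past the test 37 moved by over 1.5 times (16 with total counts, 9 without genes that share exonic bases). Of 4434 ratios of named genes 759 moved and 9 reversed. Another 70 ratios had no value after the subtraction, since nothing was left, or had been there, in the wild-type unstimulated library. Nothing was left of 15 named genes, among them Il6, Ccl5, Nos2, Ptgs2, Il1a, Rsad2, Ifit2, Gbp5, Cxcl9 and Cxcl10, whose differences ended there. No correlation changed sign. Counts were checked only for a change of over 1.5 times, so none could be labelled reversed. With total counts, the LPS split turned from 2297 higher and 2075 lower to 1550 higher and 3840 lower. The cause of such changes was not tested unless stated.

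With total counts, 3840 genes were lower with LPS by the test, and by an interval beyond 2-fold 2843 were lower in the wild-type and 2390 in the deficient pair, which follows from the shift of all genes by -0.44 and -0.38, and 31 were higher for genotype. Size factors gave 27 genes higher for genotype. Without a filter, 18 were higher and 12 lower for genotype, and the Pearson r across genes was 0.488 for LPS and 0.0945 for genotype. DESeq2's test gave 147 higher and 81 lower for genotype, and 62 of the 70 genotype calls were among its 228. The model without LPS gave 0 and 0, since LPS then counts as spread. Leaving out 1 library from a model of LPS alone, in which the lone library of an arm is assumed to vary like the others, gave 1051 to 1744 genes higher and 640 to 1464 lower. For genotype, leaving out 1 library from a model of genotype alone gave 0 higher and 0 lower, with 100 to 200 genes at an unadjusted p under 0.05.

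Without genes that share exonic bases, fewer genes were tested: 1455 were higher and 1364 lower with LPS. Beyond 2-fold, 1169 were higher and 1065 lower in the wild-type pair, 982 and 951 in the deficient pair, 225 and 115 for genotype without LPS, 198 and 238 with LPS, and 162 and 298 for the difference between LPS effects. The r was 0.860 for LPS and 0.407 for genotype. Without genes on X and Y and pseudogenes, 21 were higher and 13 lower for genotype, and its r was 0.276.

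Other fold limits moved the counts by construction. Beyond 1.5-fold, higher and lower were 2896 and 2755 (LPS, wild type), 2402 and 2531 (LPS, deficient), 823 and 419 (genotype without LPS), 794 and 872 (genotype with LPS) and 773 and 1138 (difference between LPS effects). Beyond 4-fold they were 944 and 626, 770 and 531, 102 and 62, 87 and 106, and 66 and 104. By the point ratio, genotype without LPS had 635 and 330, with LPS 685 and 669, and the difference 827 and 1023. The r of the LPS effects was 0.895 at a CPM of 10 or more and 0.861 with a pseudocount of 5, and Spearman's rho was 0.799. For genotype, r was 0.472 at a CPM of 10 or more and rho was 0.137.

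Taking 1.81% of the wild-type LPS counts from the wild-type unstimulated library lowers induced genes there by construction. Genes higher for genotype then numbered 26. The cytokine median without LPS became 0.0206 and the difference between LPS effects -0.48, the chemokine difference -1.36, and the interferon-stimulated values 0.24 and -0.17. Genotype ratio without LPS and difference became 1.93 and -1.48 for Il12b, 1.035 and -0.66 for Cd40, 2.90 and -2.94 for Il1b, and 1.35 and -1.85 for Slfn4. The values of these genes rest on small remainders, and no other share was tried. The Egln3 ratio without LPS became 0.23. The chemokine genotype ratio without LPS turned from -0.10 to 1.36. It had lain within random lists before, so it was not counted as a reversal. Of list medians that kept their direction, the LPS effect in wild type became 5.51 for cytokines, 5.30 for chemokines and 4.77 for interferon-stimulated genes. The genotype ratio without LPS became 0.39 for feedback genes, 0.76 for effectors and -0.11 for glycolysis and hypoxia genes, and the effector difference -1.15. Genotype calls ended for Chil3 (-2.08 ± 0.23 before, -2.08 ± 0.27 after), Adm (-4.37 ± 0.45, -4.27 ± 0.47) and Slfn8 (-3.26 ± 0.35, -3.00 ± 0.48), with changed spread and little changed fold. LPS calls ended for Mir692-2 (1.53 ± 0.47, 1.52 ± 0.50), Ak4 (3.96 ± 1.01, 4.77 ± 1.76), Abca1 (0.97 ± 0.28, 0.99 ± 0.31), Ctsz (0.70 ± 0.21, 0.71 ± 0.24), Gpnmb (-0.75 ± 0.21, -0.74 ± 0.23), Ticam2 (1.12 ± 0.33, 1.15 ± 0.35) and Atf3 (0.82 ± 0.24, 0.84 ± 0.26), where the fold stayed about as large or grew and the spread widened. With total counts, LPS calls ended for B2m (0.98 ± 0.20, 0.57 ± 0.19), Abca1 (0.56 ± 0.28 after), Ctsz (0.29 ± 0.20), Lck (1.78 ± 0.51, 1.38 ± 0.52), Fth1 (0.98 ± 0.21, 0.57 ± 0.20), Ticam2 (0.71 ± 0.32), Atf3 (0.41 ± 0.22) and Mir692-2 (1.15 ± 0.49), where the shift of all genes lowered the fold. The call of Mir692-2 also ended with size factors (1.58 ± 0.50) and thinned counts (1.45 ± 0.57).

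Over members with a CPM of 10 or more, list medians moved for cytokines (-0.31) and chemokines (-0.39) without LPS, mitosis (-2.37 and -2.58 for LPS, -0.25 for genotype with LPS) and glycolysis and hypoxia (-1.14 with LPS, difference -0.88). Among unmatched random lists, 12 percentiles fell inside the central 95%. For genotype these were interferon (89.5) and cholesterol (93.8) with LPS and oxidative phosphorylation without (3.56). For LPS they were LXR (8.96, deficient), oxidative phosphorylation (13.7, wild type) and lysosome (25.2 and 22). For the difference they were chemokines (94.5), antigen presentation (92.3), macrophage (95.2), LXR (97.4) and antioxidant genes (3.80), while mitosis (0.460) left it.

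The median of genes with 8mer sites without LPS was 0.0100 with sites in any annotated 3′ UTR (percentile 2.52), 0.00557 matched on expression alone (63.7), 0.00956 at a CPM of 10 or more (5.83) and 0.0159 without genes that share exonic bases (11.9).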

Other observations

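The genes below were chosen after their values were seen, and all belong to the set apart in both conditions. They are examples from the set that gave the share of neighbours, not further support for it. Reads shared between paralogs were not measured for them. Zfp992, Zfp993, Zfp991 and Zfp984 on chromosome 4 passed the test for genotype together, all higher in the deficient libraries, as did Srp54a, Srp54b and Fam177a on chromosome 12. Wdfy1, an endosomal adaptor gene of Toll-like receptor signalling, was also higher in both deficient libraries and passed.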
